A study of Mus musculus with 39 samples.

How the data were processed

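Single GFP-positive cells were sorted from adult mouse liver and picked one by one into lysis buffer for single-cell RNA sequencing, per the labels. The mice carried an inducible Cre recombinase under the control of Krt19, a keratin of bile duct epithelium, together with a GFP reporter, so a cell is green when it, or a cell it descends from, had Krt19-driven Cre. The labels named 39 cells in 1 group. They named no animal, sort, plate or sequencing run.

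Bowtie 0.12.9, eXpress 1.5.1, edgeR with no version and the mouse genome build mm9 were named in the submitters' processing notes, which give neither their order nor their settings. The deposited values were on a log2 scale, with 13568 RefSeq transcripts (12813 mRNAs and 755 non-coding RNAs) under 10061 gene symbols. The lowest log2 value, -2.58, was shared by all cells and equals 0.167 on the linear scale. It was taken as the value of a transcript with no reads, and each value was turned back to a linear one by raising 2 to it and subtracting 0.167. Scale and base were inferred from the values, and the unit is called CPM here. The linear values of a cell summed to between 351255 and 3128332, with a geometric mean of 1029230, so they carry a scaling factor per cell beyond the total. They were used as deposited. Every transcript was above 0.5 CPM in at least 2 cells, so transcripts under that level are not analysed here. Transcripts of a symbol were summed, which applied to 2155 symbols with more than 1 transcript. Of the accessions, 99.0% matched a RefSeq table of assembly GRCm38.p6 and 94.5% carried the same symbol there. That build is not the one in the processing notes, so no coordinates are given.

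Low values of a cell repeated at multiples of 1 step, taken as the worth of 1 read. The step was 0.0241 to 0.273 CPM. In cells 1 to 37 between 30.4% and 50.0% of the low values lay within 2% of 1 read of a whole multiple. The remainder included fractions, which shared reads can give. By this step 1 CPM stood for a median of 12.0 reads over 37 cells (range 3.67 to 41.5). In cells 38 and 39 too few low values followed a single step, and their depth is unknown. The fixed plan allowed for counts or a normalised linear unit. Because the file held log2 values, the normalised-unit form of the plan was applied to the back-transformed values, and no count model was fitted.

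Cells of 1 group with no named animal are not replicates. No test between cells, p-value or standard error was made. Values are given per cell or as medians and ranges, and where a count of cells has an interval, it is the exact Clopper-Pearson 95% interval, which covers the choice of cells alone. Reads without molecular identifiers are not independent molecules. Of the 12 housekeeping genes, 4 were at 0 in at least 1 cell and 35 cells had at least 1 of them at 0, so a 0 is reported only as listed at 0. No doublet caller was run. No cell was removed.

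Detection was set at 1 CPM. The marker lists, function lists and rules for named genes were fixed before the data were examined. Genes were named for being detected in the fewest cells among the lists, for leading a cluster (10 largest differences in mean log2(CPM + 1) among genes detected in at least 75% of its cells), for the 10 highest residuals of squared coefficient of variation on the mean, and for the 10 highest means among genes detected in all cells. Other named genes were picked after their values were seen, as members of the lists or to describe a group. A cluster was called by a cell type only where 3 or more of its markers were detected and the 10 leading genes did not go against the name, as markers of another type among them do. The planned clustering used Ward linkage on 10 principal components of log2(CPM + 1) of the 1000 genes with the highest residual variability (lowess span 0.3) among genes detected in at least 4 cells. Listed and ribosomal protein genes were left out, k ran from 2 to 6, every cluster needed 3 cells, and the highest silhouette decided. A second clustering on 103 cell type markers alone, and a detection threshold of 100 CPM, were chosen after seeing the data. For each list the SD over cells of its mean log2 value was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

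Both procedures were tested on simulated data made by permuting each of the 10061 genes over the 39 cells. With 200 genes raised in 10 cells, the leading-gene ranking was given those cells and cut at the 200 largest differences in place of 10. It recovered 60% of the raised genes at 4-fold, 90% at 16-fold and 99% at 64-fold. Each raised value was multiplied by the fold and then had the fold added in CPM, which also lifted transcripts with no reads. The raised genes were unlisted ones detected in at least 10 cells. Recovery where transcripts with no reads stay so was not examined. The clustering found the 10 cells at 16-fold and 64-fold, while at 4-fold the best cluster overlapped them by 32%. Of 20 data sets with permuted cells and no change, 17 still gave a clustering, with a highest silhouette of 0.170. The median silhouette over all 20 was 0.0856, which the data sets without a clustering pulled down. Of 100 unrelated lists drawn from 9646 genes, 3% passed the 95th percentile, and all 20 lists with a shared rise did. Alternatives covered thresholds, marker numbers, pseudocounts of 0.1 and 10, median-of-ratios scaling, gene filters and clustering settings. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.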

Results

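The transcriptomes of 39 single cells of the Krt19 lineage from adult mouse liver were examined, to describe which cell types the labelled cells resembled and whether they held cycling cells. The cells form 1 group in the labels, so each statement describes these cells and there is no replicate error. A median of 2985 genes per cell was detected at 1 CPM (range 1866 to 5298), and 960 at 100 CPM (range 581 to 1474). No pair of the 741 pairs of cells held identical values, and the highest Spearman correlation across genes was 0.581, between cells 2 and 3.

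Krt19 itself, the gene that drives the lineage label, was detected in 20 of 39 cells (95% interval 34.8% to 67.6%) and reached 100 CPM in 15. Where it was detected its median was 233 CPM, from 1.60 CPM in cell 28 to 20676 CPM in cell 24, and it was listed at 0 in 15 cells. Other bile duct markers were seen in different numbers of cells. Spp1, the secreted matrix protein osteopontin, was detected in 29 cells and reached 100 CPM in 24. Sox9, a transcription factor of bile duct cells, was detected in 28 cells but reached 100 CPM in 9. Krt7 was detected in 19 and Epcam in 14. Of the 270 listed genes that were measured, the fewest cells held Cdh5 and Emr1, an endothelial and a macrophage marker, each with 2.

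Clustering without any listed gene separated 6 cells, numbers 1 to 4, 38 and 39, from the other 33. The 6 cells were hepatocyte-like. Between 19 and 25 of the 28 hepatocyte markers reached 100 CPM in each of them, and the mean log2 value of that list was 8.11 to 9.55, against 0.218 to 4.49 in the 33 others. Apoa1, the main protein of high-density lipoprotein, had a median of 12087 CPM in the 6 cells and reached 100 CPM in none of the others. Fabp1, a liver fatty acid binding protein, had a median of 6207 CPM, Apoa2 had 7583 CPM and Serpina3k, a secreted protease inhibitor, had 7058 CPM. The other leading genes were Mup19, Mup14, Mup2 and Mup20 of the major urinary protein family, with LOC100048884 and Gm2083. Copies of that family are near-identical, so the split of reads between them is uncertain. Mup19, Mup14, LOC100048884, Mup2 and Mup20 also took part in forming the clusters. The periportal list had a median of 7 members at 100 CPM in these cells and the pericentral list a median of 4, with the pericentral gene Glul in 1 of the 6. Krt19 was listed below 1 CPM in all 6 cells.

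The 6 cells stood apart in other transcripts as well. Rn45s, the ribosomal RNA precursor, took 0.383% to 1.22% of their summed CPM and 8.42% to 31.2% of that of the 33 others. Lars2, a mitochondrial leucyl-tRNA synthetase, had a median of 0.982 CPM in the 6 cells and 12407 CPM in the 33. Rorb, an orphan nuclear receptor, had medians of 38444 CPM and 42.7 CPM. These are reads assigned to the 2 symbols, and whether they came from mRNA of Lars2 and Rorb was not tested. The genes that led in the 33 cells were Lars2, Fosb, Jun, Atf3, Fos, Ccdc82, Malat1, Egr1, Zfp488 and A130077B15Rik, of which 5 belong to the dissociation and immediate early list. That list held a median of 11 members at 100 CPM in 22 cholangiocyte-like cells, 10 and 5.5 in the groups of 7 and 4 cells that made up the remainder of the 33, and 0.5 in the hepatocyte-like cells. The silhouette of the 2 clusters was 0.207, and the number of clusters changed with the settings.

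**Figure D1:**
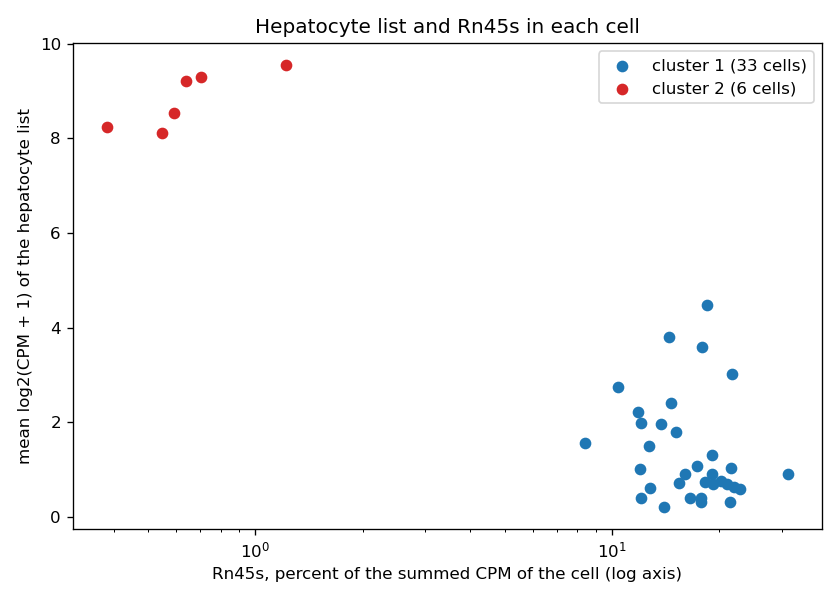
Each point is 1 of the 39 cells, with Rn45s as a percent of the summed CPM on the horizontal log axis and, on the vertical axis, the mean log2(CPM + 1) of the hepatocyte list. The 6 cells of cluster 2 lie at 1.22% or less of Rn45s with list means of 8.11 or more, and the 33 cells of cluster 1 at 8.42% or more with list means of 4.49 or less.

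Clustering on the cell type markers alone, chosen after seeing the data, gave 4 groups with a silhouette of 0.466. Of these, 22 cells formed a cholangiocyte-like group, 7 a second group, the same 6 hepatocyte-like cells the third, and 4 cells the fourth. Because the markers formed these groups, their own levels are no evidence for them, and the leading genes outside the marker lists were picked for differing between the same groups, so they only describe them. When each cell was rescaled without Rn45s, Lars2 and Rorb, also chosen after seeing the data, clustering without the listed genes gave 5 clusters. Among them were the same 7, 6 and 4 cells, and the 22 cells fell into 17 and 5. Without that rescaling or the restriction to markers, no setting tried returned the 7 or the 4 cells as clusters. By average linkage on Spearman correlation, cells 5 to 13 formed a cluster. It held cells 5 to 8 and 10 of the 7 and cells 9, 11, 12 and 13 of the 22. The same linkage clustered cells 33 to 37, joining cell 34 of the 22 with members of the 7 and the 4. It also joined cells 24, 25 and 28 of the 22 with cells 29 and 32 of the 4. At a pseudocount of 0.1, the 7 and the 4 lay in a cluster of 23 with part of the 22. The remainder of the 22 there formed clusters of cells 14 to 18 and cells 19 to 23. Several of these clusters were runs of consecutive cell numbers, and those of cells 5 to 13 and 33 to 37 crossed the marker groups.

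In the 22 cholangiocyte-like cells, Tm4sf4, a tetraspanin relative of epithelial cells, had a median of 2612 CPM and reached 100 CPM in 21 cells, against 1 of the 17 other cells. Clu, the chaperone clusterin, had a median of 15151 CPM in these cells and reached 100 CPM in all 22 and in 10 of the others. Hbegf, a growth factor of the EGF family, reached 100 CPM in 16 cells of the group and in none outside it. Of the epithelial list, 3 or more members reached 100 CPM in 21 of the 22 cells, and in 4 of the 7 cells of group 2. Cdh1, encoding E-cadherin, reached 100 CPM in 16 cells of the group and in none of the others, Krt8 in 20 and 5, and Krt18 in 22 and 8. The junction gene Jup was more even, with 10 of the 22 cells and 4 of the 7 of group 2, as was Cgn with 5 and 3. The transcription factor gene Onecut2 reached 100 CPM in 17 and 3, and the Hippo pathway target Cyr61 in 15 and 0. Atf3, a stress gene, was also among the 10 leading genes, with 17 and 5. Krt19 was detected in 15 of the 22 cells and reached 100 CPM in 11.

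The 7 cells of group 2, numbers 5 to 8, 10, 35 and 37, held markers of mesothelium, the lining of the liver surface, together with markers of fibroblasts. Among the 10 leading genes 3 were on the fibroblast list (Dcn, Col1a2 and Col3a1) and 2 on the mesothelial list (Nkain4 and Lrrn4), so genes of each type went against the other name and the group was given none. All 7 cells had 3 or more mesothelial markers at 100 CPM, and 5 had 3 or more markers of the fibroblast list, which also covers stellate cells. Those were mostly Dcn and collagen genes, with Dcn and Col1a2 in 7 cells, Col3a1 in 5 and Col1a1 in 4. Pdgfra and Acta2 reached 100 CPM in 1 cell each, and Lrat, Reln, Ngfr and Rgs5 in none. Outside the marker lists, Slpi, a secreted protease inhibitor, had a median of 1920 CPM and reached 100 CPM in 6 cells, against 2 of the 32 others. The acute phase gene Saa3 reached 100 CPM in 6 cells of the group and in none outside it. C1s1, a complement protease, reached it in 7 and 2 cells, the collagen chaperone Serpinh1 in 6 and 1, and Vim, encoding vimentin, in 7 and 5. Krt19 was detected in 5 of these cells and reached 100 CPM in 4.

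The 4 cells of group 4, numbers 29, 32, 33 and 36, held markers of blood cells and were mixed. Elane and Mpo, enzymes of neutrophil granules, had medians of 23391 and 14879 CPM and reached 100 CPM in 3 of the cells and in none of the 35 others. Prtn3, another granule protease outside the lists, had a median of 4665 CPM, and Ms4a3 of 1132 CPM. The remaining cell, number 33, held the Kupffer cell gene Clec4f at 4341 CPM. Laptm5, Nkg7, Arhgdib, Clec12a, Ly6c2 and Srgn were the other leading genes. Krt19 was under 1 CPM in all 4 cells. The group is too small and mixed for a name.

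**Figure D2:**
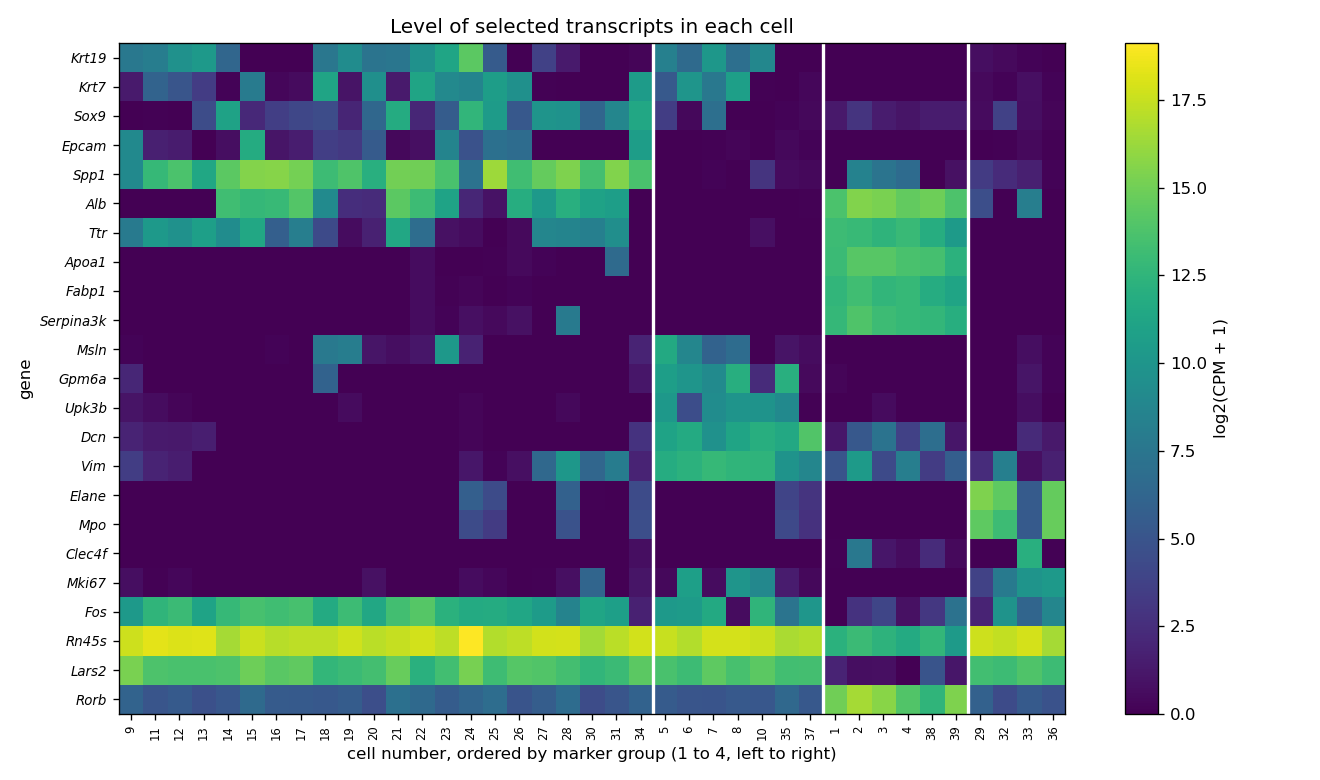
Rows are 23 genes and columns the 39 cells, in the order of the 4 marker groups, which white lines separate, and colour gives log2(CPM + 1). Apoa1 and Fabp1 are bright in the 6 cells of group 3, Spp1 in the 22 cells of group 1, Dcn in the 7 cells of group 2, and Elane in 3 of the 4 cells of group 4, while Alb is bright in group 3 and in part of group 1.

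Markers of the duct and of hepatocytes occurred together in many cells at the planned threshold. At 1 CPM, 30 cells had 3 or more cholangiocyte markers (95% interval 60.7% to 88.9%) and 35 had 3 or more hepatocyte markers (75.8% to 97.1%). Both held for 27 cells, beside 26.9 from the product of the 2 counts over 39. At 100 CPM, chosen after seeing the data, the counts were 23 and 19 with 11 cells having both, beside a product of 11.2. All 11 cells were cholangiocyte-like. The product pools all cells, and 0 of the 6 hepatocyte-like cells had 3 or more cholangiocyte markers. At this threshold 3 or more hepatocyte markers were found in 12 of the 22 cholangiocyte-like cells, 0 of the 7 of group 2 and 1 of the 4 of group 4. The same markers had formed these groups. Alb, encoding albumin, had a median of 1506 CPM in the 22 cholangiocyte-like cells and reached 100 CPM in 13 of them, against a median of 27029 CPM in the hepatocyte-like cells. Ttr, the carrier transthyretin, reached 100 CPM in 13 of the 22, Trf, encoding transferrin, in 12, and Ahsg, encoding fetuin-A, in 10. Trf also reached it in 4 of the 7 cells of group 2 and 2 of the 4 of group 4, while Ttr and Ahsg reached it in none of those. Apoa1 and Apoc3 reached it in none of the 22.

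Genes of the cell cycle were detected in several groups at low levels and reached high levels together in few cells. At 1 CPM, 26 cells had 3 or more of the 16 measured proliferation genes (49.8% to 80.9%), of which 17 were among the 22 cholangiocyte-like cells, 5 among the 7 cells of group 2 and 4 in group 4. At 100 CPM, chosen after seeing the data, 5 cells did (4.30% to 27.4%). These 5 were cells 6, 8 and 10 of group 2 and cells 32 and 36 of group 4, which were also the 5 cells with the most genes of any kind at 100 CPM (1391 to 1474, with 1213 in the next cell and a median of 887 in the cholangiocyte-like cells). None of the 22 cholangiocyte-like cells was among them, which allows a share of up to 15.4% by the exact interval, nor any of the 6 hepatocyte-like cells (up to 45.9%). Mki67, encoding a protein of dividing cells, reached 100 CPM in 6 cells, 3 in each of groups 2 and 4, with a highest value of 1768 CPM in cell 6. Top2a reached 100 CPM in 4 cells. Single proliferation genes did reach it in cholangiocyte-like cells, with Pcna, the replication clamp, in 6 of its 11 cells and Tyms, of thymidylate synthesis, in 5 of its 10. Of the arrest list, Btg2, an antiproliferative gene also induced by stress, reached 100 CPM in 18 and Btg1 in 14 of the 22 cholangiocyte-like cells. Cdkn1a, encoding the inhibitor p21, reached it in 4 of the 22. For the arrest list 11 cells had 3 or more members at 100 CPM.

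**Figure D3:**
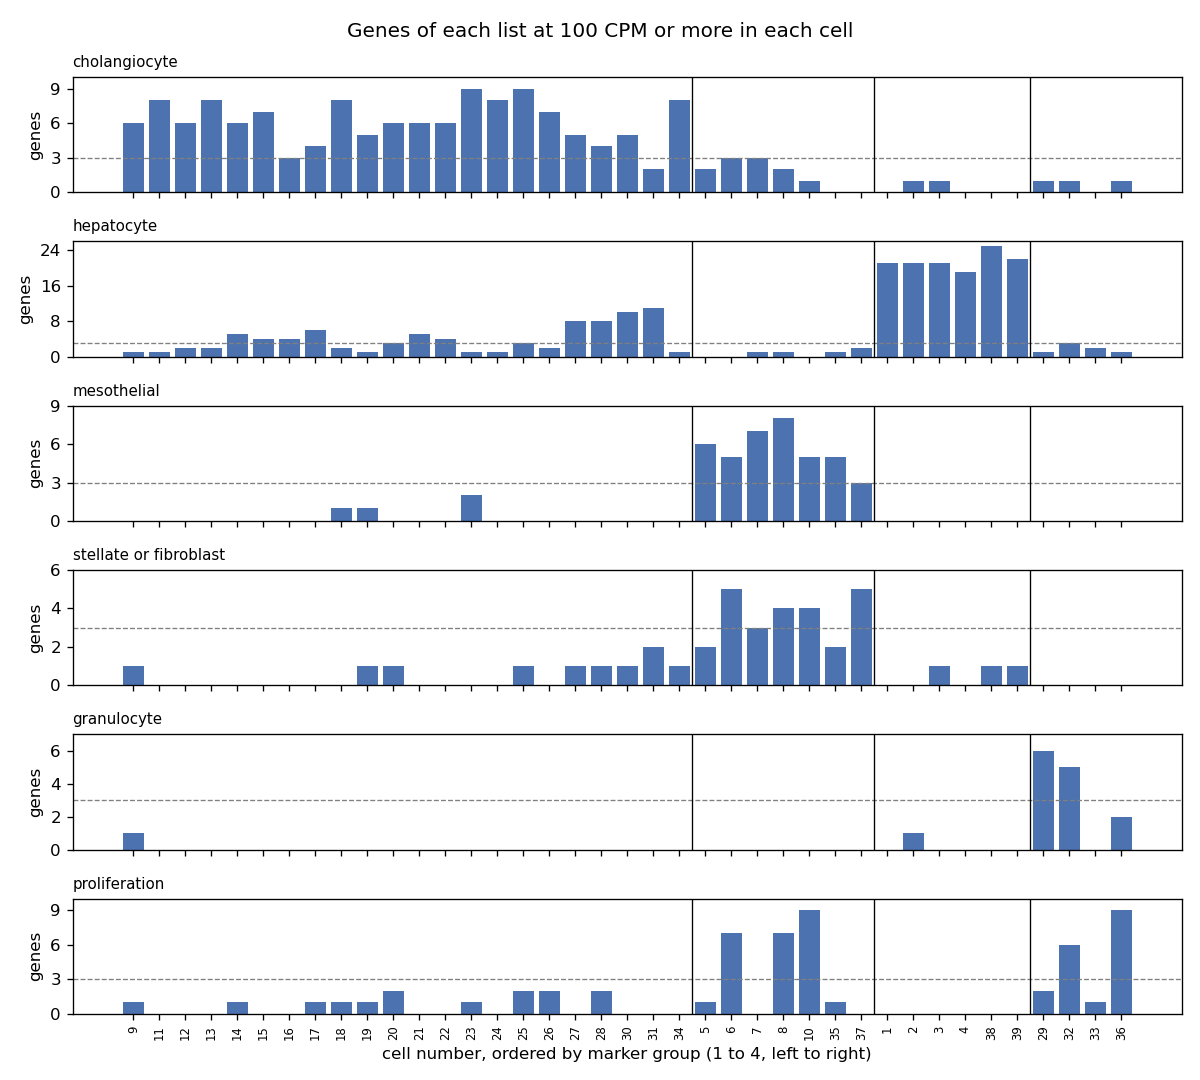
Each panel counts, for 1 list, the genes at 100 CPM or more (vertical axis) in each of the 39 cells (horizontal axis), in the order of the 4 marker groups, which vertical lines separate, and the dashed line marks 3 genes. The 6 hepatocyte-like cells hold 19 to 25 hepatocyte genes, and the proliferation panel passes the line in 5 cells of groups 2 and 4.

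Genes reported in liver progenitors were seen in part of the cells. Of that list 16 cells had 3 or more members at 100 CPM, 14 of them cholangiocyte-like. Cd44, a hyaluronan receptor, reached 100 CPM in 11 of the 22 cholangiocyte-like cells and in all 4 cells of group 4, and Prom1 in 8 of the 22 and 1 of the 4. Lgr5, a Wnt-associated receptor, was detected in 5 cells with a highest value of 6.85 CPM. Among hepatic transcription factors, 15 cells had 3 or more members at 100 CPM, 14 of them cholangiocyte-like, and Hnf4a reached 100 CPM in 4 cholangiocyte-like and 3 hepatocyte-like cells. Of the Notch list Notch2 was detected in 36 cells, and 2 cells had 3 or more members at 100 CPM. Of the Wnt list Tcf7l2 was detected in 38 cells, and 4 cells had 3 or more members at 100 CPM. The Hippo list gave 11 such cells, 8 of them cholangiocyte-like and 3 in group 2. The mesenchymal transition list gave 15, with all 7 cells of group 2 and 7 cholangiocyte-like cells among them. Antigen presentation genes gave 28 cells, the epithelial list 25 and the bile transport list 3. Immediate early genes gave 33.

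Markers of other cell types were sparse at 100 CPM. No cell had 3 endothelial markers and 1 had 3 macrophage markers. For granulocyte markers there were 2 such cells and for general leukocyte markers 3. None was found with the hepatoblast list or the T or NK cell list. Only 3 of the 10 hepatoblast genes and 4 of the 14 T or NK cell genes were measured, so this says little about absence. The B cell, erythroid and megakaryocyte lists had 2, 1 and 1 measured genes, so they could not reach 3. Members of the lists that were not measured, among them Afp, Cftr, Pecam1, Ptprc, Axin2 and Notch1, are not analysed here.

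Of the 25 fixed lists with at least 3 usable genes, 17 varied more over the cells than 95% of matched random lists. The SD over cells was 2.98 for the hepatocyte list, 2.15 for the cholangiocyte list, 2.95 for the mesothelial list and 2.55 for the immediate early list, each at percentile 100, where the random lists had medians of 0.723, 0.886, 1.03 and 1.06. Percentile 100 was also reached by the fibroblast, macrophage, granulocyte, epithelial, proliferation, pericentral and periportal lists. Above 95 were further the general leukocyte (99.99), mesenchymal transition (99.97), Hippo (99.96), endothelial (99.46), bile transport (97.75) and progenitor (97.0) lists. Hepatic transcription factors lay at 92.0, antigen presentation at 90.7, cell cycle arrest at 77.3, Notch at 68.2, housekeeping at 45.1, T or NK cell at 26.8 and hepatoblast at 8.62. The Wnt list, with an SD of 0.520 against a random median of 0.779, was at percentile 0.27. Ribosomal protein genes had an SD of 1.44 at percentile 100.

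The most variable genes for their mean were Ugt1a7c, Mup13, Rorb, Atp6ap1, Gpx2, Dmbt1, Elane, Mup19, Adat1 and Osbpl8. Dmbt1, a secreted mucosal protein, was detected in 13 cells and reached 73383 CPM. Gpx2, an epithelial glutathione peroxidase, was detected in 7 and reached 19190 CPM. Of the 71 genes detected in all 39 cells, the highest means belonged to Rn45s (168298 CPM), Rorb, Actb, Ubb, Eef1a1, Fth1, Malat1, Actg1, Ftl1 and Junb.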

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

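The 100 CPM threshold, clustering on markers alone, rescaling without Rn45s, Lars2 and Rorb, and leaving out the 6 hepatocyte-like cells were chosen after seeing the data. Leaving out cells under 50% of the median number of genes removed 0 cells, so it tested nothing and is not counted. Of the other 55 alternative values of the main results, 22 stayed within the interval or range set for them. With any value above 0, the median of genes detected per cell was 5143, and 39 cells had 3 or more cholangiocyte markers, 38 hepatocyte markers, 38 both and 37 proliferation genes. At 10 CPM there were 1745 genes per cell, 24 cells with hepatocyte markers, 16 with both and 11 with proliferation genes. At 100 CPM there were 960 genes per cell and 23, 19, 11 and 5 cells for cholangiocyte, hepatocyte, both and proliferation lists, and the median listed gene was detected in 4.5 cells in place of 11. Requiring 5 markers gave 23, 23, 15 and 12 cells in the same order. These shifts follow from the stricter or looser rule.

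The planned 2 clusters with 33 cells in the largest became 4 with 23 at a pseudocount of 0.1, and 6 with 9 by average linkage on Spearman correlation. At a pseudocount of 10 and with 500 variable genes no k left 3 cells in every cluster, which was counted as 1 cluster of 39. Markers alone gave 4 with 22, and rescaling gave 5 with 17. Without the 6 cells, again no k left 3 cells in every cluster, which was counted as 1 cluster of 33. The cause of these changes was not tested. The 6 cells formed a cluster of their own under 8 of the 10 alternatives that kept all cells and did not rest on the markers alone. The number of lists above the 95th percentile was 17 to 19 throughout. Of 125 percentiles of single lists under the alternatives, 50 left the sampling interval of the planned value. Thinning to equal counts was not run, because the values are not counts. Depth limits low detection, since 1 CPM stood for 3.67 to 41.5 reads.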

Other observations

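The threshold of 1000 CPM for Alb and the tests of library preparation, hepatocyte RNA, reads from the hepatocyte-like libraries and low levels by cell number were chosen after their results had been seen in part. The test by cell number replaced 1 by clusters of correlated cells, which also gave a higher share within clusters but rested on expression itself. The labels hold 1 group, so no explanation that needs a contrast of groups was tested. A further test of read transfer on Alb was set aside, because its transcripts had been chosen for being low in all other cells, which fixed its outcome.

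Single listed genes were high in part of a group. Rgs5, a regulator of G-protein signalling best known from pericytes, reached 100 CPM in 8 of the 22 cells and in no other cell, with a highest value of 3743 CPM. Msln, encoding mesothelin, reached 100 CPM in 3 cells of group 2 and also in cells 18, 19 and 23 of the cholangiocyte-like group, where its values were 207, 276 and 1179 CPM. Gpc3, on the hepatoblast list, reached 100 CPM in 5 of the 7 cells of group 2 and in no other cell. Krt23 reached it in 5 cells, all cholangiocyte-like.

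Xist, the transcript of the inactive X chromosome, reached 100 CPM in 10 cells, with 5463 CPM in cell 21 and 4413 CPM in cell 15. Of the 3 measured Y-linked genes, at least 1 reached 100 CPM in 2 cells, numbers 19 and 23, where Eif2s3y had 190 CPM and Uty 1343 CPM. No cell had both, beside 0.513 from the product of the counts over 39.

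Cells held low levels of transcripts abundant in 1 other cell: 268 transcripts were at 1000 CPM or more in 1 cell and under 100 CPM in every other, and 12 cells had at least 10 of them. Transcripts of the source cell were counted as seen above 0.05 CPM. Pairs numbered at most 3 apart and of different marker groups saw a median of 71.4% of them (15 pairs, quartiles 35.4% to 74.6%). It was 27.3% in pairs further apart and of 1 group (147 pairs). Near pairs of 1 group had 38.5% (57 pairs, quartiles 21.4% to 78.9%) and far pairs of different groups 23.1% (237 pairs). Pairs with the same source cell are not independent. The 15 pairs had only cells 7, 8, 26, 28, 33 and 34 as sources, and most had cell 33 or 34. The first median exceeded the second by 44.16 percentage points (15.2 to 50.5 when near meant 1 to 5 apart). Passage of reads between neighbouring libraries predicts this direction, if cell numbers follow their preparation. The same contrast with its sign changed, -44.16, argues against low expression shared by cells of 1 type as the whole source, and is not a second test. Nearness did not account for all of it. Of the transcripts of cell 24, cell 28 saw 100% and cell 29 saw 90.9%, which were 4 and 5 apart. Nearer to cell 24, cell 25 saw 72.7%, cell 23 saw 36.4% and cell 26 saw 18.2%. Cell 38 saw 80.0% of the transcripts of cell 19 and 69.2% of those of cell 8, but it had the most genes detected of any cell (5298). In near cells the transcripts had a median of 0.00304% of their source level and a 95th percentile of 0.682%. They were chosen for being under 100 CPM in every other cell, which capped this share, so passage at higher levels was not examined. Of the values, 22.8% were at 1 CPM or more in near cells and 15.5% in far ones. How many detections passage of reads could account for stays open.

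The hepatocyte-like cells could owe their separation to how the libraries were made. Rn45s, Lars2 and Rorb were left out and each cell was rescaled. The hepatocyte list still differed by 8.044 on the log2 scale between the clusters (7.44 before). The lowest of the 6 cells had a list mean of 8.81 after rescaling and the highest of the 33 had 4.78. Rn45s took at most 31.2% of the summed CPM of any cell, so rescaling could hardly change so large a difference. The outcome was fixed in advance, and no conclusion is drawn from it. Rn45s differed with no overlap, by a gap of 3.458 on the log2 scale, and all 6 cells were of 1 marker group. A difference in library preparation and a difference in cell type cannot be told apart for Rn45s, Lars2, Rorb and the immediate early genes, because no cell of another type shared the pattern of the 6.

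Alb reached 1000 CPM in 12 of the 22 cholangiocyte-like cells (1318 to 20694 CPM), or 4.88% to 76.6% of the median of the hepatocyte-like cells. Reads passing from the hepatocyte-like libraries were argued against, because the median level of 20 of their abundant transcripts, relative to those libraries, was under 10% of that of Alb in 12 of 12 cells. For hepatocyte RNA or a hepatocyte in the same well, which single picking of GFP-positive cells would limit, the test had 3 versions: the same 20 transcripts gave 12 of 12 cells, but 9 were of the Mup family, whose level differs between the sexes, and 20 outside that family gave 8 of 12, with cells 27, 28, 30 and 31 not excluded by the median. The last version asks whether all abundant transcripts came along. The expected level was set by Alb and the lowest ratio to Alb among the hepatocyte-like cells. At least 6 of those 20 lay under 10% of it in each of the 12 cells, with Apoa2, Fabp1, Saa1 and Serpina1e among them in all 12. Each hepatocyte-like cell held out gave 0 of 20. That is no independent control, because the 20 were picked for reaching 100 CPM in all 6 of those cells. In cells 14 to 17, 21 and 22, with Alb at 25.8% to 76.6% of the hepatocyte-like median, 10 to 14 of the 20 lay that low. This argues against RNA of hepatocytes like these 6 as the whole source of Alb there, although Trf and Ttr each reached 100 CPM in 9 of the 12. In cells 23, 26 to 28, 30 and 31 Alb was at 4.88% to 15.6%. Loss of transcripts from so little hepatocyte RNA was not modelled, so the question stays open for them. The 12 cells were numbered 14 to 31, but cholangiocyte-like cells 18, 19, 20, 24 and 25, within that span, were not among them. Outside the span, cholangiocyte-like cells 9, 11, 12, 13 and 34 were not among them either. Whether a batch or a cell state set Alb stays open because the labels name no batch.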
